A study of Mus musculus with 33 samples.

How the data were processed

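RNA was sequenced from inflammatory monocytes (IM), tumour-associated macrophages (TAM) and CD8 T cells sorted from orthotopic KCKO pancreatic tumours of C57BL/6 mice, 33 libraries in 12 groups. Per the labels' protocols, tumours were dissociated with collagenase, cells were sorted by flow cytometry, RNA was purified with a micro column kit, and libraries were made with the TruSeq RNA kit V2, which does not mark strand, and sequenced on an Illumina HiSeq instrument. The protocols name injections of empty or IL-12 microspheres (2 mg of beads) on day 10 without stating which groups received empty ones, and they give no day of harvest. Per the submitters' processing notes, Trimmomatic 0.36, FastQC 0.11.8, STAR 2.6.0c, Subread, featureCounts and Salmon were used with build GRCm38; the notes give no role, order or annotation release.

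The values came from 9 tables deposited by the authors, 1 for each treated group against the unirradiated group of its population, with 53735 gene names each. Per the file headers these are DESeq2 results, and neither the DESeq2 version nor the design formula is stated. The first column holds a normalised signal per gene, per the file headers the mean over libraries of counts divided by size factors; it was identical in the 3 tables of a population, as in 1 fit of 4 groups with shared controls. The log2 fold changes, per the file headers treated over unirradiated, were shrunken, since their ratio to the Wald statistic was highest between levels of 30 and 300 and fell at lower levels. The Wald statistic deposited by the authors is a score whose 2-sided normal probability equalled the deposited p-value. The adjusted p-value deposited by the authors covers the genes left after a filter on mean level, 13876 to 19273 per table. No per-library values or counts accompany the tables, so the depth per library is unknown and no interval that needs it is given.

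A gene was called when its deposited adjusted p was below 0.05, with the direction taken from the Wald statistic, and it is said to rise or fall only then. The standard error of a fold change was taken as its ratio to the statistic. Differences between treatments within a population, the interaction (combination minus both single effects) and differences between populations were tested as statistic times a standard error shared by the tables, with a normal test and Benjamini-Hochberg adjustment over all genes with a p. Within a population the covariance through the shared controls was left out, which makes the test conservative. On simulated data for IM (17666 genes), 63% of genes with a log2 difference of 1 between the combination and SBRT were recovered, 4% at 0.5, and 0.636% of unchanged genes had a p below 0.05, while the interaction recovered 43% at 1. For CD8 (18497 genes) the difference recovered 63% at 1 and 10% at 0.5, and the interaction 40% at 1; for TAM (18146 genes) the interaction recovered 8% at 1. With the control variance removed, an alternative, 4.99%, 4.65% and 5.14% of unchanged genes in IM, TAM and CD8 had a p below 0.05 for the combination minus SBRT, near the nominal 5%, and 95%, 76% and 94% of genes with a difference of 1 were recovered. These data were simulated with the shared controls that this variance assumes.

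In all, 33 lists were fixed before the data were examined, as were the comparisons, the thresholds, the rule for named genes and the alternatives, apart from those stated as chosen later. The 17 gene lists covered the interferon gamma and type I interferon responses, MHC class I and class II presentation, inflammatory and alternatively activated macrophage genes, chemokines and receptors, inhibitory ligands and enzymes of myeloid cells, cytotoxic effectors, T cell exhaustion, naive and memory T cells, IL-12 signalling, cell cycle, p53 targets, glycolysis and hypoxia, complement and phagocytic receptors, and extracellular matrix. The other 16 held markers of T, CD4 and regulatory T, natural killer, B and plasma cells, macrophages, monocytes, neutrophils, dendritic, mast, epithelial, acinar, fibroblast, endothelial and erythroid cells, mitochondrially encoded genes and dissociation stress genes. Some genes stand in more than 1 list, and several markers are expressed by the sorted cells themselves. Lists were tested on the Wald statistics with cameraPR of limma 3.58.1 (R 4.3.3) at a preset correlation of 0.01, 2-sided, adjusted over the 297 list tests. On simulated statistics of independent genes the list test called 3% of random lists of 20 genes and 82% with 20 genes shifted by 1 SD. These rates do not cover lists of co-regulated genes, for which the p-values may be too small.

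Named genes were the 8 highest and 8 lowest fold changes after the combination, and 5 each way after a single treatment, among called genes with a level of at least 50, leaving out predicted genes, pseudogenes and antigen receptor segments. To these came up to 4 members per list and comparison with the smallest adjusted p, a fixed set of immune genes, and the 5 largest differences each way. Members of gene families with similar copies (Gbp, Iigp1 and Tgtp1, H2, Ly6, Sectm1, Klr, Gzm, C1q and tubulin genes) may share reads, as may overlapping genes such as Psmb9 and Tap1 or Tgtp1 and Olfr56, and their values are uncertain to that extent. Positions come from GENCODE M21 for GRCm38, which held 28453 of the 53735 names and 557 of 563 named genes or list members; Selm is the older symbol of a selenoprotein gene. Alternatives were other thresholds, other filters on level, median-centred fold changes, an empirical null (statistics divided by their robust spread where above 1), removal of the shared control variance, and for lists a correlation of 0.05, ranks and a level of at least 50. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.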

Results

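Gene expression was measured by RNA sequencing in 3 immune cell populations sorted from tumours of C57BL/6 mice. The mice carried KCKO pancreatic ductal adenocarcinoma cells implanted in the tail of the pancreas. The populations were inflammatory monocytes (IM, CD45+CD11b+Ly6C+Ly6G-), tumour-associated macrophages (TAM, CD45+CD11b+Ly6G-F4/80+ with moderate Ly6C) and CD8 T cells (CD45+CD8+). Stereotactic body radiotherapy (SBRT) was given as 4 fractions of 6 Gy on days 6 to 9, and interleukin 12 (IL-12) as microspheres holding 0.5 µg, injected into the tumour on day 10. Each population had 4 groups: unirradiated, SBRT, IL-12 and both, here called the combination. IM and CD8 had 3 libraries per group. TAM had 3 in the IL-12 group and 2 in each of the others.

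The authors' deposited tables compare each treated group with the unirradiated group of its population. They give a mean normalised level, a log2 fold change and an adjusted p from the authors' DESeq2 Wald test for each gene, and no value for a single library. The depth of each library is therefore unknown, as is how many libraries showed each direction. The p-values measure the spread between these libraries, since the labels do not say that each came from a separate mouse. A number in parentheses after a gene is its deposited log2 fold change, ± the standard error implied by the Wald statistic where given, and genes said to have risen or fallen had a deposited adjusted p below 0.05. For each gene list the median log2 fold change of its members and the adjusted p of limma's cameraPR test are given, with "set higher" or "set lower" where the test passed. Calls after adjustment over the members alone are counted as "within the list". Positions are of build GRCm38.

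**Figure D1:**
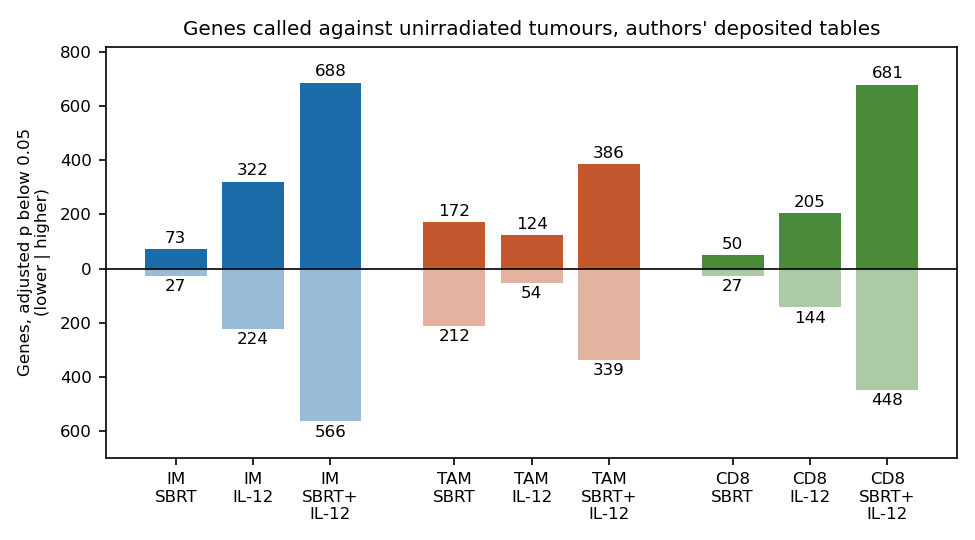
Number of genes with a deposited adjusted p below 0.05 in each of the 9 comparisons with unirradiated tumours, higher and lower, by population and treatment. The combination gave 1254 genes in IM, 725 in TAM and 1129 in CD8, more than either single treatment in the same population.

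In the authors' deposited table, SBRT alone raised a small set of interferon-inducible genes in inflammatory monocytes. Among them were the GTPase genes Iigp1 (0.76 ± 0.12, adjusted p = 6.7e-07) and Tgtp1 (0.53 ± 0.11, adjusted p = 0.0019). Nos2, the inducible nitric oxide synthase on chromosome 11, 78920787 to 78960254, rose too (0.84 ± 0.19, adjusted p = 0.0043). So did Il12rb1, a subunit of the IL-12 receptor (0.93 ± 0.15, adjusted p = 6.3e-06). The largest increases also included Sectm1a (1.13), Itpka (1.07) and Rmi2 (0.99) and the inhibitory ligand gene Pdcd1lg2 (0.95). The largest decreases were those of Nat8l (-1.06), H2-T9 (-1.05), Mlxipl (-0.90), Arhgap6 (-0.89) and Klra9 (-0.86). Of 19273 genes tested in the deposited table, 100 changed, 73 higher and 27 lower, and 5 of them by a log2 fold change of at least 1.

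As sets, interferon, antigen presentation and glycolysis genes were higher in IM after SBRT, while the p53 and cell cycle lists did not pass. Of 25 interferon gamma response genes, 4 rose (12 within the list, median 0.34, set higher, cameraPR adjusted p = 2.5e-33), with Gbp4 (0.64) among them. Of 22 type I interferon response genes, 2 rose (4 within the list, median 0.28, set higher, cameraPR adjusted p = 6.0e-17). Of 15 MHC class I presentation genes, 4 rose (7 within the list, median 0.25, set higher, cameraPR adjusted p = 4.8e-21), including the peptide transporter Tap1 (0.36) and the proteasome subunit Psmb10 (0.38). Of 13 MHC class II presentation genes, 0 were called (6 higher and 0 lower within the list, median 0.32, set higher, cameraPR adjusted p = 3.1e-10). Of 24 glycolysis and hypoxia genes, 0 were called (4 higher and 0 lower within the list, median 0.29, set higher, cameraPR adjusted p = 1.0e-17). Of 11 inhibitory ligand and enzyme genes, 2 rose (3 within the list, median 0.13, set higher, cameraPR adjusted p = 3.6e-05, and from 7.1e-04 to 0.16 in the alternatives). Cd274, the gene of PD-L1, did not pass (0.55 ± 0.15, adjusted p = 0.057). Of 25 p53 targets, 0 were called (0 within the list, median 0.06, cameraPR adjusted p = 0.73). Cdkn1a, which encodes the cell cycle inhibitor p21, did not pass either (0.09, adjusted p = 0.99). Of 30 cell cycle genes, 0 were called (0 within the list, median -0.05, cameraPR adjusted p = 0.70). Of 19 complement and phagocytic receptor genes, 0 were called (0 within the list, median 0.21, set higher, cameraPR adjusted p = 7.7e-04). Of 20 alternatively activated macrophage genes, 1 rose (1 within the list, median 0.08, set higher, cameraPR adjusted p = 0.026, and from 0.11 to 0.34 in the alternatives). Of 17 extracellular matrix and protease genes, 0 were called (0 higher and 1 lower within the list, median -0.19, set lower, cameraPR adjusted p = 0.010, and from 0.031 to 0.053 in the alternatives). Of 24 cytotoxic effector genes, 0 were called (1 higher and 2 lower within the list, median -0.15, set lower, cameraPR adjusted p = 0.0062, and from 0.0048 to 0.054 in the alternatives). Of 10 B and plasma cell markers, 0 were called (0 within the list, median -0.06, set lower, cameraPR adjusted p = 0.016, and from 0.049 to 0.79 in the alternatives, turned to set higher at a level of at least 50). In the same libraries the mitochondrially encoded genes, a sign of RNA quality, were lower (median -0.29, cameraPR adjusted p = 3.7e-07). Natural killer cell markers were lower as well (median -0.34, cameraPR adjusted p = 6.7e-06).

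IL-12 alone changed more genes in inflammatory monocytes. Nos2 (1.51 ± 0.19, adjusted p = 3.4e-12) and Il12rb1 (1.33 ± 0.15, adjusted p = 5.3e-15) rose in the authors' deposited table. Interferon-inducible genes rose with them: Ly6a (1.49), Iigp1 (1.46), Gbp2b (1.33) and Tgtp1 (1.07). The genes that fell most were Fcrls (-1.96 ± 0.24, adjusted p = 3.1e-13), the lectin gene Cd209a (-1.76), the haemoglobin scavenger receptor Cd163 (-1.75), Cd177 (-1.50) and Lrg1 (-1.50). Of 16829 genes tested in the deposited table, 546 changed, 322 higher and 224 lower, and 80 of them by a log2 fold change of at least 1. When the Wald statistics were divided by their robust spread over all genes (an empirical null), 297 genes passed.

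Interferon and antigen presentation lists were higher in IM after IL-12, and lists of alternatively activated macrophage and matrix genes lower. Of 25 interferon gamma response genes, 16 rose (18 within the list, median 0.50, set higher, cameraPR adjusted p = 4.7e-56). Of 22 type I interferon response genes, 13 rose (19 within the list, median 0.48, set higher, cameraPR adjusted p = 6.9e-40). Of 15 MHC class I presentation genes, 10 rose (13 within the list, median 0.46, set higher, cameraPR adjusted p = 2.2e-49). Of 13 MHC class II presentation genes, 6 rose (7 within the list, median 0.45, set higher, cameraPR adjusted p = 6.9e-14), with H2-Ab1 (0.75) and H2-Eb1 (0.72) among them. Of 20 alternatively activated macrophage genes, 5 fell (6 within the list, median -0.19, set lower, cameraPR adjusted p = 7.2e-07, and from 2.0e-05 to 0.13 in the alternatives), including Ccl24 (-1.08) and Trem2 (-0.53). Of 17 extracellular matrix and protease genes, 6 fell (3 higher and 8 lower within the list, median -0.16, set lower, cameraPR adjusted p = 6.0e-07, and from 1.2e-04 to 0.42 in the alternatives), including the genes of fibronectin, Fn1 (-1.10), and of a protease inhibitor, Timp1 (-1.46). Of 18 inflammatory macrophage genes, 3 rose (4 within the list, median 0.15, set higher, cameraPR adjusted p = 7.5e-06). Of 24 glycolysis and hypoxia genes, 2 rose (9 within the list, median 0.31, set higher, cameraPR adjusted p = 1.6e-15). Of 19 complement and phagocytic receptor genes, 3 rose (5 higher and 1 lower within the list, median 0.10, set higher, cameraPR adjusted p = 0.0060, and from 0.043 to 0.17 in the alternatives). Of 30 cell cycle genes, 0 were called (0 within the list, median 0.29, set higher, cameraPR adjusted p = 2.0e-08). Of 11 inhibitory ligand and enzyme genes, 2 rose (3 higher and 1 lower within the list, median 0.05, set higher, cameraPR adjusted p = 0.031, and from 0.084 to 0.88 in the alternatives). The fractalkine receptor gene Cx3cr1 (-1.12, adjusted p = 4.6e-08) and the cytokine receptor gene Flt3 (-1.36, adjusted p = 1.2e-06) fell. The mitochondrially encoded genes were again lower (median -0.27, cameraPR adjusted p = 1.2e-04).

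The combination gave the largest count in inflammatory monocytes. In the authors' deposited table Nos2 (2.16 ± 0.20, adjusted p = 3.3e-25) and Il12rb1, on chromosome 8, 70808449 to 70821424 (2.03 ± 0.15, adjusted p = 1.1e-35), rose most. The other 6 of the 8 largest increases were those of Selm (2.01), Sectm1a (1.99), Ly6a (1.94), Inpp5j (1.88), Gbp2b (1.87) and Iigp1 (1.83). Inpp5j overlaps Pla2g3 on the other strand, and both were called higher, so the reads of the pair could not be told apart. Cd209a, on chromosome 8, 3743397 to 3748984, fell most (-2.31 ± 0.22, adjusted p = 9.0e-23). Next came Fcrls (-2.30), Cd177 (-2.16), Dmkn (-2.05), Cd163 (-1.99), Ednrb (-1.95), Lrg1 (-1.94) and St6gal1 (-1.93). Of 18660 genes tested in the deposited table, 1254 changed, 688 higher and 566 lower, and 171 of them by a log2 fold change of at least 1. The empirical null left 336, and of the genes named here and below Ciita, Mrc1, Ndrg1, C1qa, C1qb, C1qc, Ms4a7, Batf3 and Clec9a lost their calls (adjusted p from 0.057 to 0.54).

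As sets, interferon and antigen presentation genes of both classes were higher in IM after the combination, and matrix genes lower. Of 25 interferon gamma response genes, 19 rose (20 within the list, median 0.73, set higher, cameraPR adjusted p = 1.0e-74), among them Tgtp1 (1.44) and Gbp4 (1.49). Of 22 type I interferon response genes, 14 rose (17 within the list, median 0.51, set higher, cameraPR adjusted p = 2.3e-26). Of 15 MHC class I presentation genes, 12 rose (13 within the list, median 0.64, set higher, cameraPR adjusted p = 4.7e-56), for example Tap1 (0.79) and Psmb9 (0.75). Of 13 MHC class II presentation genes, 8 rose (11 within the list, median 0.51, set higher, cameraPR adjusted p = 2.5e-19), for example H2-Ab1 (0.98) and H2-DMb2 (0.83). Ciita, the class II transactivator, rose too (0.48, adjusted p = 0.040). Of 20 alternatively activated macrophage genes, 1 rose and 7 fell (2 and 7 within the list, median -0.29, set lower, cameraPR adjusted p = 5.9e-04, and from 0.0042 to 0.46 in the alternatives), with Chil3 (-0.98) and Mrc1 (-0.99) lower. Of 18 inflammatory macrophage genes, 3 rose (3 within the list, median 0.18, set higher, cameraPR adjusted p = 9.9e-06). Arg1 (0.46, adjusted p = 0.088), Cxcl9 (0.22, adjusted p = 0.65) and Il1b (-0.28, adjusted p = 0.38) did not pass. Of 11 inhibitory ligand and enzyme genes, 4 rose and 2 fell (5 and 2 within the list, median 0.01, set higher, cameraPR adjusted p = 4.0e-05, and from 7.5e-04 to 0.69 in the alternatives), with Cd274 higher (1.31 ± 0.15, adjusted p = 2.8e-15). Of 17 extracellular matrix and protease genes, 2 rose and 6 fell (2 and 8 within the list, median -0.34, set lower, cameraPR adjusted p = 1.2e-07, and from 4.4e-05 to 0.16 in the alternatives), with Fn1 (-1.66) and Timp1 (-1.73) lower.

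Glycolysis and complement lists were higher in IM after the combination, as after each single treatment, and monocyte markers moved both ways. Of 24 glycolysis and hypoxia genes, 8 rose (14 within the list, median 0.35, set higher, cameraPR adjusted p = 1.9e-16), including Ndrg1 (0.77) and Pfkfb3 (0.70). Of 19 complement and phagocytic receptor genes, 5 rose (6 higher and 3 lower within the list, median 0.11, set higher, cameraPR adjusted p = 0.0011, and from 0.015 to 0.073 in the alternatives), including C1qb (0.71) and Fcgr4 (0.89). Of 24 chemokine and receptor genes, 3 fell (1 higher and 3 lower within the list, median 0.01, cameraPR adjusted p = 0.085), led by Cx3cr1 (-1.92 ± 0.17, adjusted p = 3.0e-25). Of 10 monocyte markers, 2 rose and 4 fell (3 and 5 within the list, median -0.27, set lower, cameraPR adjusted p = 0.0011, and from 0.0066 to 0.47 in the alternatives), with Vcan (-1.23) and F13a1 (-1.03) lower. Of 17 IL-12 signalling genes, 2 rose and 2 fell (2 and 2 within the list, median -0.02, cameraPR adjusted p = 0.29), with Socs1 (1.10) higher and Stat4 (-1.50) lower. Of 30 cell cycle genes, 1 rose (0 within the list, median 0.27, set higher, cameraPR adjusted p = 1.8e-06). Of 25 p53 targets, 3 rose and 1 fell (3 and 1 within the list, median 0.09, cameraPR adjusted p = 0.29). Mitochondrially encoded genes were lower in these libraries as well (median -0.32, cameraPR adjusted p = 4.0e-05).

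Whether the combination differed from either single treatment in IM was tested on differences of the deposited effects. Against SBRT alone, 67 of 32818 genes differed, 41 higher and 26 lower. Lowest were Cd209a (difference -2.02 ± 0.33, adjusted p = 5.4e-06), Cd163 (-1.96), Dmkn (-1.95), Cd177 (-1.93) and Fcrls (-1.83). Highest were Nos2 (difference 1.27 ± 0.27, adjusted p = 0.0033), Selm (1.39), Clic5 (1.16) and Inpp5j (1.16) and the scavenger receptor Cd36 (1.15). By cameraPR, the combination stood above SBRT for the interferon gamma response (adjusted p = 5.4e-33), MHC class I (adjusted p = 2.1e-28) and MHC class II (adjusted p = 1.1e-07). It stood below SBRT for alternatively activated genes (adjusted p = 1.0e-10). That list was set higher after SBRT, a call lost in all 3 alternatives, and lower after the combination, a call lost by ranks (adjusted p = 0.46). Against IL-12 alone, 0 genes differed by the normal test (225 at an unadjusted p below 0.05). By cameraPR the combination stood above IL-12 for the interferon gamma response (adjusted p = 1.8e-15), MHC class I (adjusted p = 1.5e-07) and class II (adjusted p = 5.0e-05).

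The interaction is the combination minus the sum of both single effects. In IM it passed for 1 gene (340 at an unadjusted p below 0.05), the pseudogene Olfr650-ps1 (0.07, adjusted p = 0.00022), chosen after its value was seen. With the own standard error of each table this call was lost (adjusted p = 1.0) and 1 other gene passed, with a lower value. No interaction of a single gene in IM thus held in both of these settings. Type I interferon (adjusted p = 5.6e-12) and interferon gamma lists (6.3e-04) lay below the summed single effects (cameraPR), as chance in controls could give. All these tests left out the covariance through the shared controls. With the control variance removed, 355 genes differed from SBRT (200 higher and 155 lower), 17 from IL-12 (8 and 9) and 4 by interaction (3 and 1).

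In tumour-associated macrophages, SBRT alone raised targets of the tumour suppressor p53 and lowered cell cycle genes. Phlda3, a p53 target on chromosome 1, 135766119 to 135769136, rose most in the authors' deposited table (3.49 ± 0.19, adjusted p = 6.2e-73). Cdkn1a, on chromosome 17, 29090976 to 29100727 (1.41 ± 0.16, adjusted p = 6.2e-16), and Bbc3, the gene of the pro-apoptotic protein Puma (1.58 ± 0.18, adjusted p = 1.6e-14), rose with it. The largest increases also included Psrc1 (2.02), Ephx1 (1.84) and Zmat3 (1.66). Among the p53 targets, 13 of 25 rose (14 within the list, median 0.70, set higher, cameraPR adjusted p = 2.4e-69). Among the cell cycle genes, 20 of 30 fell (27 within the list, median -0.88, set lower, cameraPR adjusted p = 2.5e-58), among them Stmn1 (-1.23), Mcm5 (-1.12), Mcm6 (-1.02) and Ccna2 (-1.18). Mki67, a proliferation marker, did not pass (-0.01, adjusted p = 1.0). Of 18436 genes tested in the deposited table, 384 changed, 172 higher and 212 lower, and 122 of them by a log2 fold change of at least 1. The empirical null left 219, and Ido1 lost its call (adjusted p = 0.066).

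The largest decreases in TAM after SBRT were those of the myelin protein gene Pmp22 (-2.35 ± 0.24, adjusted p = 4.0e-19), Lrg1 (-2.19), Prg4 (-1.80) and Fcrls (-1.65) and the chemokine gene Cxcl13 (-1.59) in the authors' deposited table. Among the interferon gamma response genes, 3 of 25 rose (12 within the list, median 0.32, set higher, cameraPR adjusted p = 2.8e-15). Among the type I interferon response genes, 3 of 22 rose (11 within the list, median 0.47, set higher, cameraPR adjusted p = 4.1e-21), including the antiviral gene Mx1 (1.01). Among the MHC class I presentation genes, 1 of 15 rose (6 within the list, median 0.28, set higher, cameraPR adjusted p = 2.4e-08). Among the MHC class II presentation genes, 0 of 13 were called (0 within the list, median -0.03, cameraPR adjusted p = 0.90). Among the inhibitory ligand and enzyme genes, 2 of 11 rose (4 within the list, median 0.25, set higher, cameraPR adjusted p = 1.4e-04), with Pdcd1lg2 (0.95) and Ido1 (0.96). Among the extracellular matrix and protease genes, 3 of 17 fell (3 within the list, median -0.12, set lower, cameraPR adjusted p = 4.1e-04, and from 0.0071 to 0.068 in the alternatives). Among the glycolysis and hypoxia genes, 1 of 24 fell (1 within the list, median -0.08, set lower, cameraPR adjusted p = 0.030, and from 0.033 to 0.14 in the alternatives). Among the fibroblast markers, 2 of 12 fell (2 within the list, median -0.51, set lower, cameraPR adjusted p = 3.3e-07), namely Col1a1 (-1.47) and Bgn (-0.99). In the same libraries markers of tumour and ductal epithelium (median -0.35, cameraPR adjusted p = 0.0047) and of T cells (median -0.26, cameraPR adjusted p = 0.0021) were lower. The mitochondrially encoded genes were lower too (median -0.28, cameraPR adjusted p = 0.0026).

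IL-12 alone raised interferon-inducible genes in TAM. In the authors' deposited table Ifit3 (0.98), Mx1 (0.87), Gbp4 (0.89) and Tgtp1 (0.85) rose. Il12rb1 rose as well (0.78 ± 0.15, adjusted p = 1.6e-04). The largest increases included those of the RNA-binding protein gene Elavl3 (2.01), Plac8 (1.40), Klrk1 (1.21) and Gbp2b (1.07). The largest decreases were those of Fcrls (-1.33), Emp1 (-1.27), St6gal1 (-1.18), Htra3 (-1.15) and Cxcl13 (-1.14). Of 19042 genes tested in the deposited table, 178 changed, 124 higher and 54 lower, and 24 of them by a log2 fold change of at least 1, of which 9 were higher and 15 lower. Here the sign of the fold change opposed that of the Wald statistic for 2795 genes, 1 of them called, so the statistic gave the direction. The other 8 tables held 22 to 594 such genes, 0 of them called. For Elavl3 the statistic times the standard error shared by the tables of TAM gives an effect of 0.86, well below the deposited fold change, so its size is uncertain.

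The interferon lists of TAM were higher after IL-12, the cell cycle list lower, and the p53 list did not pass. Among the interferon gamma response genes, 11 of 25 rose (20 within the list, median 0.58, set higher, cameraPR adjusted p = 6.7e-54). Among the type I interferon response genes, 12 of 22 rose (16 within the list, median 0.68, set higher, cameraPR adjusted p = 5.2e-54). Among the MHC class I presentation genes, 3 of 15 rose (9 within the list, median 0.34, set higher, cameraPR adjusted p = 2.8e-23). Among the MHC class II presentation genes, 0 of 13 were called (0 within the list, median 0.18, set higher, cameraPR adjusted p = 2.2e-04). Among the IL-12 signalling genes, 2 of 17 rose (2 within the list, median 0.15, set higher, cameraPR adjusted p = 4.1e-04, and from 0.0036 to 0.062 in the alternatives). Among the alternatively activated macrophage genes, 1 of 20 fell (2 within the list, median -0.22, set lower, cameraPR adjusted p = 4.5e-05), namely the lectin gene Cd209f (-0.80). Among the extracellular matrix and protease genes, 2 of 17 fell (2 within the list, median -0.12, set lower, cameraPR adjusted p = 3.6e-05), namely Fn1 (-1.05) and Timp2 (-0.63). Among the inflammatory macrophage genes, 0 of 18 were called (1 higher and 0 lower within the list, median 0.16, set higher, cameraPR adjusted p = 0.0032). Among the cell cycle genes, 0 of 30 were called (0 higher and 1 lower within the list, median -0.36, set lower, cameraPR adjusted p = 2.1e-14). Among the fibroblast markers, 0 of 12 were called (0 within the list, median -0.22, set lower, cameraPR adjusted p = 0.011). Among the complement and phagocytic receptor genes, 1 of 19 fell (1 within the list, median -0.06, set lower, cameraPR adjusted p = 0.034, and from 0.066 to 0.14 in the alternatives). Among the p53 targets, 0 of 25 were called (1 higher and 0 lower within the list, median -0.09, cameraPR adjusted p = 0.76). Nos2 (0.69, adjusted p = 0.076) and Cd274 (0.53, adjusted p = 0.10) did not pass. T cell markers (median -0.32, cameraPR adjusted p = 4.5e-07) and mitochondrially encoded genes (median -0.32, cameraPR adjusted p = 1.5e-04) were lower.

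After the combination both p53 targets and interferon-inducible genes rose in TAM. In the authors' deposited table the p53 targets Phlda3 (3.31 ± 0.19, adjusted p = 2.7e-65) and Cdkn1a (1.29 ± 0.16, adjusted p = 5.2e-13) rose. Cpt1c (2.48), Psrc1 (1.76), Zmat3 (1.71), Bbc3 (1.57), Trp53inp1 (1.54), Ephx1 (1.53) and Plekhg4 (1.47) made up the rest of the 8 largest increases with Phlda3. Nos2 (1.30 ± 0.23, adjusted p = 4.9e-06), Cd274 (0.82), Ido1 (1.12) and Mx1 (1.24) rose as well. The largest decreases were those of Fcrls (-1.86), Lrg1 (-1.81), Prg4 (-1.76), Itga6 (-1.72), S1pr1 (-1.68), Sorbs3 (-1.59), Selp (-1.48) and Kntc1 (-1.46). Of 17224 genes tested in the deposited table, 725 changed, 386 higher and 339 lower, and 156 of them by a log2 fold change of at least 1, of which 75 were higher and 81 lower. The empirical null left 247, and Cd86, Mrc1, Ifng and Ccl5 lost their calls (adjusted p from 0.051 to 0.22).

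The lists of TAM after the combination showed higher p53 and interferon genes and lower cell cycle genes. Among the p53 targets, 13 of 25 rose (14 within the list, median 0.49, set higher, cameraPR adjusted p = 1.9e-50). Among the cell cycle genes, 19 of 30 fell (25 within the list, median -0.82, set lower, cameraPR adjusted p = 2.6e-47), with Mcm5 (-1.34) and Foxm1 (-1.32) among them. Among the interferon gamma response genes, 14 of 25 rose (19 within the list, median 0.60, set higher, cameraPR adjusted p = 1.9e-35). Among the type I interferon response genes, 9 of 22 rose (16 within the list, median 0.67, set higher, cameraPR adjusted p = 9.8e-28). Among the MHC class I presentation genes, 7 of 15 rose (10 within the list, median 0.41, set higher, cameraPR adjusted p = 4.8e-15). Among the MHC class II presentation genes, 0 of 13 were called (0 within the list, median 0.12, cameraPR adjusted p = 0.085). Among the inflammatory macrophage genes, 3 of 18 rose (4 higher and 1 lower within the list, median 0.23, set higher, cameraPR adjusted p = 2.4e-05), including the costimulatory gene Cd86 (0.58). Among the alternatively activated macrophage genes, 1 of 20 rose and 3 fell (1 and 4 within the list, median -0.18, set lower, cameraPR adjusted p = 0.0089, and from 0.055 to 0.097 in the alternatives), with the mannose receptor gene Mrc1 (-0.78) lower. Among the inhibitory ligand and enzyme genes, 4 of 11 rose (4 within the list, median 0.21, set higher, cameraPR adjusted p = 3.2e-04, and from 0.0031 to 0.25 in the alternatives). Among the IL-12 signalling genes, 3 of 17 rose (4 within the list, median 0.23, set higher, cameraPR adjusted p = 1.5e-05). Among the extracellular matrix and protease genes, 3 of 17 fell (3 within the list, median -0.12, set lower, cameraPR adjusted p = 1.1e-04). Among the fibroblast markers, 2 of 12 fell (2 within the list, median -0.32, set lower, cameraPR adjusted p = 1.7e-05).

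Ifng, the gene of interferon gamma, rose in the macrophage gate after the combination (1.22 ± 0.30, adjusted p = 0.0031), at a level of 135 in the authors' deposited table. Klrk1 (0.93) and Ccl5 (0.84) rose with it. Among the cytotoxic effector genes, 3 of 24 rose and 1 fell (3 and 1 within the list, median 0.16, set higher, cameraPR adjusted p = 0.023, and from 0.015 to 0.12 in the alternatives). Among the T cell markers, 0 of 13 were called (0 within the list, median 0.16, cameraPR adjusted p = 0.22).

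Differences were tested within TAM in the same way. Against IL-12 alone, 27 of 32375 genes differed, 23 higher and 4 lower. Highest were Phlda3 (difference 3.44 ± 0.25, adjusted p = 3.0e-37), Cpt1c (2.78), Psrc1 (2.41), Ephx1 (2.13) and Arhgap32 (1.62). Lowest were Prg4 (-1.44), Vars2 (-1.30) and Elavl3 (-1.22), the last from the effect of 0.86 after IL-12. By cameraPR the p53 targets stood above IL-12 alone (adjusted p = 8.1e-77) and the cell cycle list below it (adjusted p = 1.7e-25). Against SBRT alone, 1 gene differed (292 at an unadjusted p below 0.05), the mitochondrial valyl-tRNA synthetase gene Vars2 (difference -1.62 ± 0.31, adjusted p = 0.0033). By cameraPR the combination stood above SBRT for the interferon gamma response (adjusted p = 1.2e-10), IL-12 signalling (adjusted p = 1.1e-06) and cytotoxic genes (adjusted p = 6.2e-06). T cell markers stood above SBRT too (adjusted p = 3.2e-08).

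The interaction in TAM passed for 4 genes (378 at an unadjusted p below 0.05). They were Pmp22 (difference 2.22 ± 0.41, adjusted p = 0.0028), Adm (1.98) and Vars2 (-1.86) and the unnamed clone RP23-172K2.12 (-2.01), chosen after its value was seen. Type I interferon (adjusted p = 1.8e-18) and interferon gamma genes (6.6e-09) lay below the summed single effects (cameraPR), as chance in controls could give. Removing the control variance gave 160 genes against IL-12 (98 higher and 62 lower, a more even split than that of the 27), 42 against SBRT (26 and 16) and 11 by interaction (8 and 3). In simulated data for 18146 genes, the main test of combination minus SBRT recovered 25% of log2 changes of 1 and 0% of 0.5.

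In CD8 T cells, SBRT alone changed few genes. Il7r, the interleukin 7 receptor gene, fell in the authors' deposited table (-0.86 ± 0.22, adjusted p = 0.030). Bub1, a mitotic checkpoint kinase gene, rose (0.55 ± 0.14, adjusted p = 0.030), as did Cdkn1a (0.59 ± 0.15, adjusted p = 0.032) and the interferon-inducible Gbp6 (0.63). The largest increases were those of the pancreatic trypsinogen gene Prss2 (1.09), Bzrap1 (1.05), the costimulatory ligand gene Cd80 (0.92), Ankle1 (0.88) and Msc (0.88). Besides Il7r, the largest decreases were those of F2rl1 (-0.90), Rab6b (-0.88) and Klhl8 (-0.85) and the B cell gene Cd79b (-0.86). Gzmb (0.52, adjusted p = 0.12), Tcf7 (-0.70, adjusted p = 0.23) and Ifng (0.38, adjusted p = 0.50) did not pass. Of 16359 genes tested in the deposited table, 77 changed, 50 higher and 27 lower, and 5 of them by a log2 fold change of at least 1, of which 2 were higher and 3 lower. Il7r, Bub1, Cdkn1a, Msc, F2rl1, Rab6b and Cd79b lost their calls when every gene with a p was adjusted (adjusted p from 0.057 to 0.084), and under the empirical null every gene named here did. The count was 40 when every gene with a p was adjusted, 75% of them higher against 64.9%, and 1 under the empirical null.

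As sets, cell cycle and cytotoxic genes were higher in CD8 after SBRT and naive and memory genes lower. For cell cycle genes, 1 of 30 rose (6 within the list, median 0.25, set higher, cameraPR adjusted p = 1.5e-17). For naive and memory T cell genes, 1 of 15 fell (1 higher and 2 lower within the list, median -0.38, set lower, cameraPR adjusted p = 2.3e-06). For cytotoxic effector genes, 0 of 24 were called (2 higher and 0 lower within the list, median 0.15, set higher, cameraPR adjusted p = 0.0015, and from 0.0073 to 0.081 in the alternatives). For interferon gamma response genes, 2 of 25 rose (3 within the list, median 0.14, set higher, cameraPR adjusted p = 4.9e-07). For type I interferon response genes, 0 of 21 were called (0 within the list, median 0.19, set higher, cameraPR adjusted p = 3.2e-04). For MHC class I presentation genes, 0 of 15 were called (0 within the list, median 0.09, set higher, cameraPR adjusted p = 0.031, and from 0.044 to 0.10 in the alternatives). For exhaustion genes, 0 of 17 were called (0 within the list, median -0.04, cameraPR adjusted p = 0.52). For p53 targets, 1 of 24 rose (3 within the list, median 0.01, cameraPR adjusted p = 0.35). Myeloid genes were higher in the same gate: macrophage markers (median 0.24, cameraPR adjusted p = 3.9e-04) and complement and phagocytic receptor genes (median 0.22, cameraPR adjusted p = 0.0040). For inflammatory macrophage genes, 1 of 18 rose (2 within the list, median 0.27, set higher, cameraPR adjusted p = 6.5e-06). For chemokine and receptor genes, 0 of 24 were called (0 within the list, median 0.17, set higher, cameraPR adjusted p = 0.0038). For alternatively activated macrophage genes, 0 of 20 were called (0 within the list, median 0.23, set higher, cameraPR adjusted p = 0.031, and from 0.019 to 0.12 in the alternatives). Acinar pancreas markers were higher (median 0.23, cameraPR adjusted p = 2.0e-06). B and plasma cell markers were lower (median -0.35, cameraPR adjusted p = 6.9e-06). For fibroblast markers, 0 of 12 were called (0 within the list, median -0.21, set lower, cameraPR adjusted p = 0.026, and from 0.024 to 0.29 in the alternatives).

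IL-12 alone raised cell cycle genes in CD8 T cells. Mki67 (0.51 ± 0.12, adjusted p = 0.0025) and Bub1 (0.81 ± 0.14, adjusted p = 1.3e-05) rose in the authors' deposited table. Gzmb, the granzyme B gene on chromosome 14, 56258838 to 56262260, rose too (0.59 ± 0.16, adjusted p = 0.020), as did Gzmk (0.62). The largest increases were those of Furin (1.30), Cetn4 (1.22), Il1rl1 (1.18), Fes (1.18) and Ly6a (1.17). Fes lies 639 bp from Furin on the same strand, and both were called higher. The largest decreases were those of Mturn (-1.02) and Slc43a1 (-1.02), the transcriptional repressor gene Bach2 (-0.99), Usp28 (-0.99) and Acss1 (-0.99). Of 13876 genes tested in the deposited table, 349 changed, 205 higher and 144 lower, and 14 of them by a log2 fold change of at least 1. The empirical null left 24, of which 83.3% were higher against 58.7%. Mki67, Gzmb, Gzmk, Mturn, Slc43a1, Bach2, Usp28 and Il7r lost their calls there (adjusted p from 0.076 to 0.46).

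After IL-12 the cell cycle and cytotoxic lists of CD8 were higher and the naive and memory list lower. For cell cycle genes, 20 of 30 rose (28 within the list, median 0.55, set higher, cameraPR adjusted p = 2.7e-57), including Cdk1 (0.79) and Ube2c (0.76). For cytotoxic effector genes, 2 of 24 rose (6 higher and 1 lower within the list, median 0.24, set higher, cameraPR adjusted p = 8.2e-05). For naive and memory T cell genes, 2 of 15 fell (1 higher and 7 lower within the list, median -0.52, set lower, cameraPR adjusted p = 1.5e-10), including Il7r (-0.90). For IL-12 signalling genes, 1 of 17 rose and 1 fell (3 and 1 within the list, median 0.09, set higher, cameraPR adjusted p = 0.0096, and from 0.052 to 0.17 in the alternatives). For interferon gamma response genes, 1 of 25 rose (1 within the list, median 0.15, set higher, cameraPR adjusted p = 1.7e-05). For type I interferon response genes, 0 of 21 were called (0 within the list, median 0.19, set higher, cameraPR adjusted p = 0.0020). For MHC class I presentation genes, 0 of 15 were called (0 within the list, median 0.09, set higher, cameraPR adjusted p = 6.5e-04). For inflammatory macrophage genes, 0 of 18 were called (3 higher and 0 lower within the list, median 0.13, set higher, cameraPR adjusted p = 0.016, and from 0.011 to 0.076 in the alternatives). For inhibitory ligand and enzyme genes, 0 of 11 were called (0 within the list, median 0.08, set higher, cameraPR adjusted p = 0.022, and from 0.051 to 0.28 in the alternatives). For exhaustion genes, 0 of 17 were called (1 higher and 0 lower within the list, median 0.07, cameraPR adjusted p = 0.38). For p53 targets, 0 of 24 were called (0 within the list, median -0.12, cameraPR adjusted p = 0.10). Ifng (0.64, adjusted p = 0.060) and Tcf7 (-0.76, adjusted p = 0.077) did not pass. Acinar markers were higher (median 0.24, cameraPR adjusted p = 1.8e-05) and fibroblast markers lower (median -0.20, cameraPR adjusted p = 0.016, and from 0.053 to 0.17 in the alternatives).

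After the combination nearly the whole cell cycle list rose in CD8 T cells, with granzyme genes and Ifng. In the authors' deposited table Mki67 (0.86 ± 0.12, adjusted p = 1.9e-10), Rrm2 (1.13), Birc5 (1.02) and Cdk1 (0.99) rose. So did Gzmb (1.05 ± 0.16, adjusted p = 4.5e-08), Gzma (1.07), Ifng (0.80 ± 0.21, adjusted p = 0.0038) and the perforin gene Prf1 (0.60). Tcf7, a transcription factor gene of naive and memory T cells on chromosome 11, 52252371 to 52283014, fell (-0.84 ± 0.25, adjusted p = 0.014). The largest increases were those of Cetn4 (1.89 ± 0.19, adjusted p = 1.5e-19), Sulf2 (1.81), Furin (1.70), P2rx7 (1.67), P2rx3 (1.57), Il1rl1 (1.47), Ano7 (1.46) and Serpine2 (1.43). P2rx3 overlaps Ssrp1 (both called higher) and Tmie overlaps Als2cl (both called lower) on the other strand. The kit does not mark strand, so P2rx3 and Tmie are uncertain. The largest decreases were those of Tmie (-1.57), Camkk1 (-1.28) and Acss1 (-1.28), the interferon gamma receptor subunit Ifngr2 (-1.18), Nckap5l (-1.13), Bach2 (-1.11), Wbscr27 (-1.10) and Matk (-1.06). Of 15115 genes tested in the deposited table, 1129 changed, 681 higher and 448 lower, and 58 of them by a log2 fold change of at least 1. The empirical null left 188, of which 85.6% were higher against 60.3%. Ifng, Prf1, Tcf7, Wbscr27, Il12rb1, S1pr1, Tigit and Pmaip1 lost their calls there (adjusted p from 0.065 to 0.51).

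Cell cycle, cytotoxic, IL-12 signalling and glycolysis lists were higher in CD8 after the combination, and the naive and memory list lower. For cell cycle genes, 29 of 30 rose (29 within the list, median 0.75, set higher, cameraPR adjusted p = 4.0e-98). For cytotoxic effector genes, 8 of 24 rose and 1 fell (9 and 1 within the list, median 0.17, set higher, cameraPR adjusted p = 1.0e-06). Tbx21, which encodes T-bet, did not pass (0.14, adjusted p = 0.71). For IL-12 signalling genes, 4 of 17 rose and 1 fell (5 and 2 within the list, median 0.16, set higher, cameraPR adjusted p = 1.6e-04, and from 0.0039 to 0.13 in the alternatives), with Il12rb1 (0.71) higher. For naive and memory T cell genes, 5 of 15 fell (9 within the list, median -0.54, set lower, cameraPR adjusted p = 2.9e-10), including S1pr1 (-0.82). For exhaustion genes, 2 of 17 fell (4 within the list, median -0.09, cameraPR adjusted p = 0.12), namely Tigit (-0.55) and Nr4a3 (-0.78). Pdcd1, the gene of PD-1, did not pass (-0.21, adjusted p = 0.52). For glycolysis and hypoxia genes, 3 of 24 rose (6 higher and 1 lower within the list, median 0.17, set higher, cameraPR adjusted p = 2.4e-05). For p53 targets, 2 of 24 rose (3 higher and 1 lower within the list, median -0.06, cameraPR adjusted p = 0.89), namely Cdkn1a (0.94) and Pmaip1 (0.43). For interferon gamma response genes, 1 of 25 rose (1 within the list, median 0.22, set higher, cameraPR adjusted p = 1.2e-04). For type I interferon response genes, 0 of 21 were called (0 within the list, median 0.13, cameraPR adjusted p = 0.081). Lists of myeloid and stromal genes were lower in the same gate. For macrophage markers, 0 of 12 were called (1 higher and 3 lower within the list, median -0.45, set lower, cameraPR adjusted p = 1.2e-04). For MHC class II presentation genes, 1 of 13 fell (1 within the list, median -0.32, set lower, cameraPR adjusted p = 3.3e-05). For complement and phagocytic receptor genes, 0 of 19 were called (0 within the list, median -0.30, set lower, cameraPR adjusted p = 6.5e-04). For chemokine and receptor genes, 1 of 24 rose and 2 fell (1 and 2 within the list, median -0.16, set lower, cameraPR adjusted p = 0.016, and from 0.0072 to 0.096 in the alternatives). For extracellular matrix and protease genes, 3 of 17 fell (4 within the list, median -0.22, set lower, cameraPR adjusted p = 0.0015, and from 0.012 to 0.067 in the alternatives). For fibroblast markers, 1 of 12 fell (2 within the list, median -0.46, set lower, cameraPR adjusted p = 0.0024).

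Against SBRT alone, 25 of 33127 genes differed in CD8 T cells after the combination, 22 higher and 3 lower. Highest were Sulf2 (difference 2.09 ± 0.32, adjusted p = 4.3e-07), P2rx3 (2.06), Cetn4 (1.96), Furin (1.66) and P2rx7 (1.36). Lowest among named genes were Il11ra2 (-1.40) and Ypel3 (-0.73). By cameraPR the combination stood above SBRT for cell cycle (adjusted p = 5.8e-49) and glycolysis and hypoxia (adjusted p = 1.1e-07). It stood below SBRT for complement genes (adjusted p = 1.8e-10) and macrophage markers (adjusted p = 1.0e-13). Against IL-12 alone, 1 gene differed (440 at an unadjusted p below 0.05), a variable segment of the immunoglobulin kappa locus (-0.56, adjusted p = 3.2e-05). The same segment was the 1 gene to pass the interaction (-0.64, adjusted p = 0.00043), where 609 had an unadjusted p below 0.05. It had a level of 28.2 and was chosen after its values were seen. With the own standard error of each table both calls were lost (adjusted p = 1.0). Cell cycle genes stood above IL-12 alone (adjusted p = 1.9e-19) and MHC class II genes below it (adjusted p = 5.4e-06, cameraPR). By interaction, acinar (adjusted p = 6.9e-23), macrophage (5.9e-09) and type I interferon lists (4.5e-04) lay below the summed single effects. Chance in the controls was not excluded. At a level of at least 50 the counts were 49, 0 and 0, and with the control variance removed 461, 53 and 14. Of the 461 genes, 232 were higher and 229 lower, so the excess of higher genes among the 25 did not hold in that setting.

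**Figure D2:**
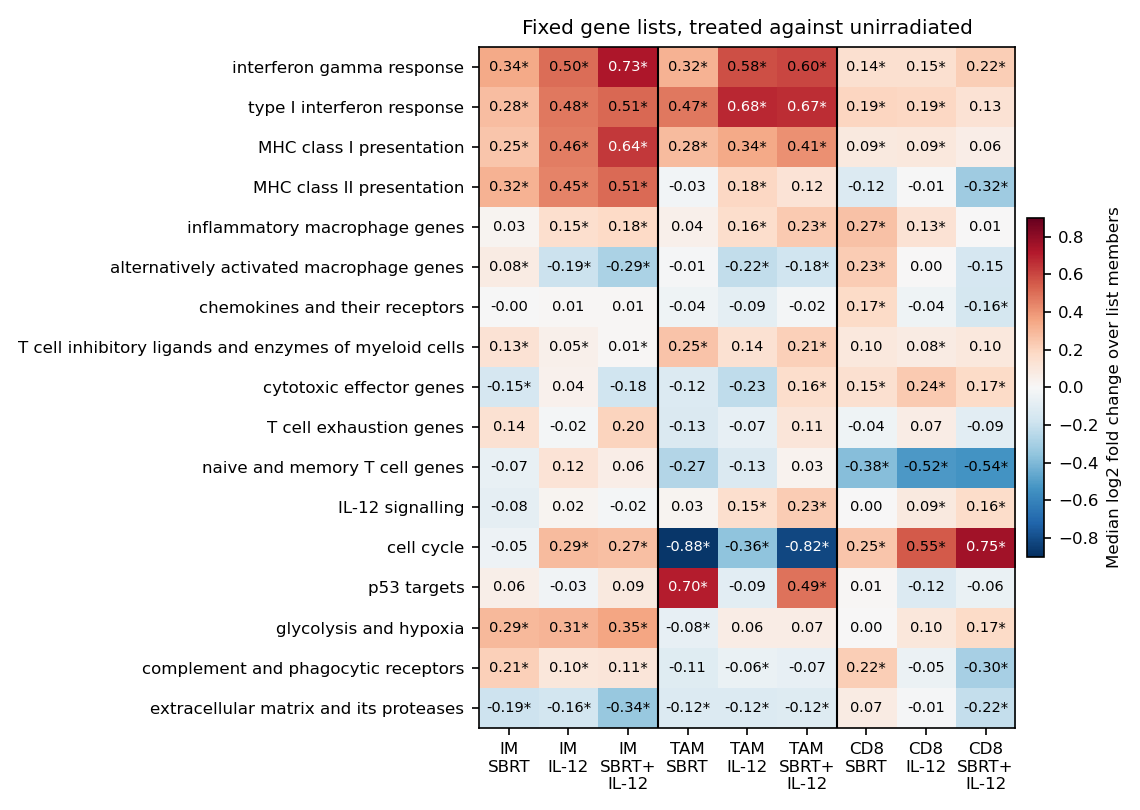
Median log2 fold change of each gene list (vertical axis) in each of the 9 comparisons (horizontal axis), from the deposited tables. An asterisk marks a cameraPR adjusted p below 0.05, and cell cycle genes range from -0.88 in TAM after SBRT to 0.75 in CD8 after the combination.

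Responses to the same treatment were then compared between populations, on differences of the deposited effects. After SBRT, p53 targets had lower effects in IM than in TAM, for example Phlda3 (difference -3.02 ± 0.29, adjusted p = 3.1e-20), Bbc3 (difference -1.58 ± 0.24, adjusted p = 9.7e-08) and Zmat3 (-1.60). The p53 list was lower in IM than in TAM (adjusted p = 3.2e-42) and higher in TAM than in CD8 (adjusted p = 3.4e-33, cameraPR). Between IM and TAM 81 genes differed after SBRT, between IM and CD8 6, and between TAM and CD8 192. Dtl (-1.98), Pkmyt1 (-1.89) and Cdc45 (-1.67), genes of DNA replication and mitotic entry, were lower in TAM than in CD8. After IL-12 the counts were 21, 147 and 65. Cd163 (-1.51) was lower and Iigp1 (0.96) higher in IM than in TAM. Tgtp1 (1.31) was higher and Sulf2 (-1.75) lower in IM than in CD8. The differences for single treatments were chosen after the data were seen, and the fold changes of each population were shrunken separately.

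After the combination 285 genes differed between IM and TAM, 574 between IM and CD8 and 718 between TAM and CD8. Uhrf1 (difference 2.27 ± 0.32, adjusted p = 7.3e-09) and Mcm5 (1.91) were higher in IM than in TAM. Phlda3 (-2.61), Gria3 (-2.38) and Zmat3 (-1.89) were lower. Kntc1 (difference -2.39 ± 0.32, adjusted p = 3.3e-10), Pclaf (-2.29) and Bub1 (-2.23) were lower in TAM than in CD8. Nos2 (1.91), Selm (1.86) and Tgtp1 (1.80) were higher in IM than in CD8. Sulf2 (difference -2.73 ± 0.30, adjusted p = 3.3e-15), Cd209a (-2.08) and Cx3cr1 (-1.77) were lower. By cameraPR the cell cycle list was higher in IM than in TAM (adjusted p = 2.0e-54) and lower in IM (4.4e-14) and TAM (5.6e-107) than in CD8. Interferon gamma (adjusted p = 2.1e-23) and MHC class II lists (1.1e-19) were higher in IM than in CD8. In CD8 class II was lower with myeloid lists, so other cells in the gate may contribute. Class II was also higher in IM than in TAM (adjusted p = 8.6e-08).

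Genes called in the same direction after the combination were compared between populations by Fisher's exact test (hypergeometric, 1-sided), chosen after the data were seen. It takes co-regulated genes as independent, so its p-values may be too small. Tumours or cells shared between gates were not excluded. IM and TAM shared 141 higher genes, against 14.9 for independent lists (exact p = 1.4e-101), and 61 lower genes, against 10.4 (exact p = 8.5e-30). IM and CD8 shared 84 higher, against 27.2 (exact p = 7.5e-21), and 29 lower, against 13.4 (exact p = 8.1e-05). TAM and CD8 shared 17 higher, against 13.8 (exact p = 0.22), and 16 lower, against 8.08 (exact p = 0.0074).

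**Figure D3:**
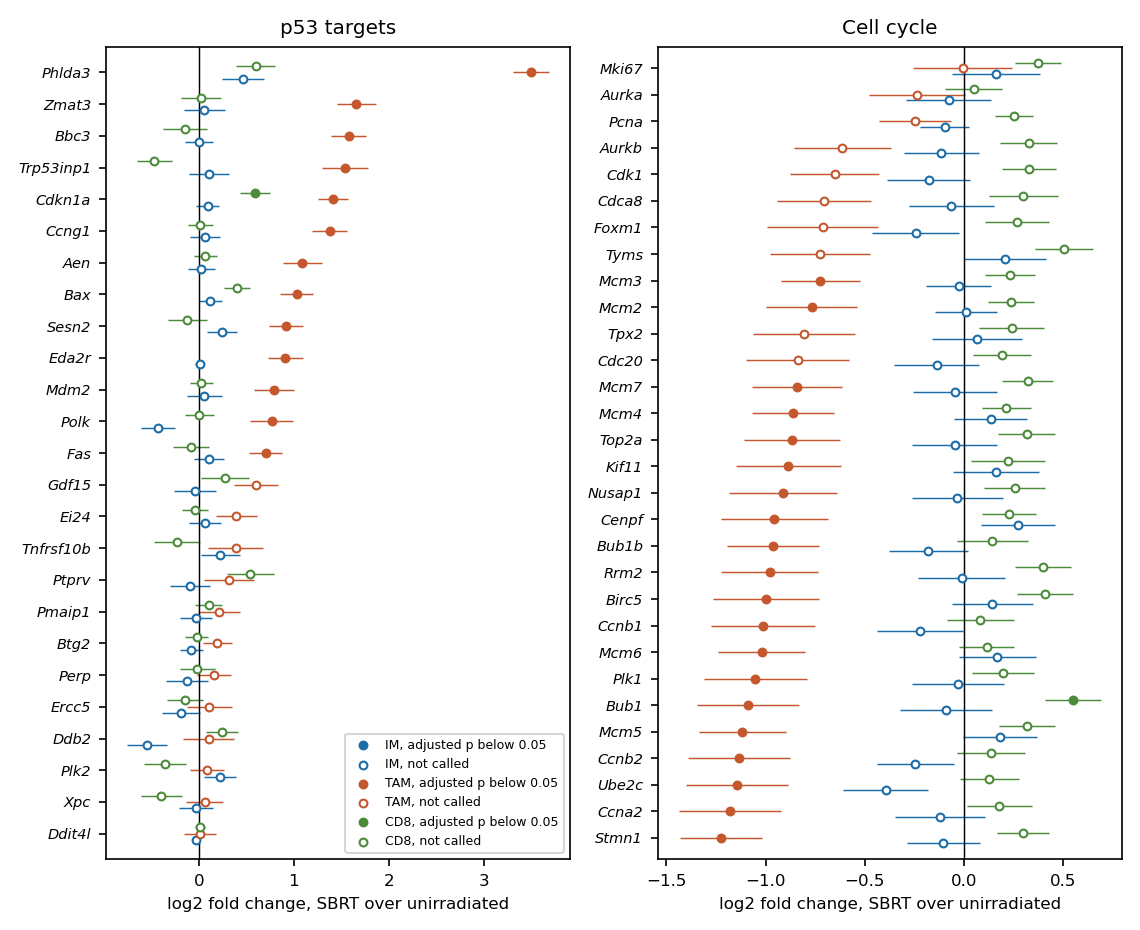
Deposited log2 fold change after SBRT (horizontal axis) of each p53 target and cell cycle gene in IM, TAM and CD8, with bars of 1 implied standard error and filled points for an adjusted p below 0.05. In TAM 13 p53 targets lay above 0 and 20 cell cycle genes below 0 with filled points.

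Markers of other cell types that the gates could hold were read from the same deposited tables, as medians with cameraPR adjusted p-values. Acinar markers in IM were at 0.19 (adjusted p = 9.7e-05) after SBRT, 0.25 (adjusted p = 1.7e-05) after IL-12 and -0.05 (adjusted p = 0.54) after the combination. By interaction they lay below the sum of the single effects (adjusted p = 3.1e-17). In TAM they were at 0.06 (adjusted p = 0.32) after SBRT, 0.14 (adjusted p = 0.040, and from 0.0033 to 0.12 in the alternatives) after IL-12 and -0.09 (adjusted p = 0.22) after the combination. In CD8 after the combination they were at -0.09 (adjusted p = 0.038, and from 0.022 to 0.22 in the alternatives). Fibroblast markers in IM were at -0.26 (adjusted p = 0.0020, and from 0.012 to 0.091 in the alternatives) after SBRT, -0.16 (adjusted p = 0.093) after IL-12 and -0.22 (adjusted p = 0.019, and from 0.0047 to 0.22 in the alternatives) after the combination. Natural killer cell markers in IM were at -0.15 after IL-12 (adjusted p = 0.17) and -0.30 after the combination (adjusted p = 0.0017). Neutrophil markers in IM were at -0.15 (adjusted p = 0.0054) after SBRT, -0.01 (adjusted p = 0.39) after IL-12 and -0.18 (adjusted p = 0.035, and from 0.024 to 0.17 in the alternatives) after the combination. T cell markers in IM were at 0.14 (adjusted p = 0.043, and from 0.12 to 0.22 in the alternatives) after SBRT, -0.02 (adjusted p = 0.76) after IL-12 and -0.09 (adjusted p = 0.34) after the combination, and in CD8 after the combination at -0.13 (adjusted p = 0.032, and from 0.013 to 0.17 in the alternatives). Macrophage markers passed in neither IM (adjusted p from 0.076 to 0.72) nor TAM (adjusted p from 0.23 to 0.52). In IM after the combination the neighbouring genes C1qa (0.60), C1qb (0.71) and C1qc (0.74) nevertheless rose and Ms4a7 (-0.87) fell. Among the monocyte markers in TAM after IL-12, 3 of 10 rose and 2 fell (4 and 2 within the list, median 0.12, set higher, cameraPR adjusted p = 0.0020, and from 0.011 to 0.60 in the alternatives).

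Dendritic cell markers passed in none of the 9 comparisons (cameraPR adjusted p from 0.23 to 0.99). In IM after the combination Batf3 (0.58) and Clec9a (0.73) rose, Flt3 (-1.46) and Cd209a fell, and the median was 0.24 while the mean was -0.14. CD4 and regulatory T cell markers (adjusted p from 0.18 to 0.98), endothelial markers (adjusted p from 0.056 to 0.90) and dissociation stress genes (adjusted p from 0.071 to 0.94) passed in none either. Mast cell and basophil markers gave adjusted p-values from 0.29 to 0.97, with 1 marker at a level of at least 10 in IM and 0 in TAM and CD8. Erythroid markers were at 0.25 in IM after the combination (adjusted p = 0.013, and from 0.016 to 0.22 in the alternatives) and -0.06 in TAM after SBRT (adjusted p = 1.2e-04). Among the B and plasma cell markers in TAM after SBRT, 2 of 11 fell (1 higher and 4 lower within the list, median -0.17, set lower, cameraPR adjusted p = 0.0016, and from 0.0097 to 0.63 in the alternatives). For B and plasma cell markers in CD8 after the combination, 0 of 11 were called (0 within the list, median -0.27, set lower, cameraPR adjusted p = 0.010). The lists' correlation between genes was preset to 0.01, since it could not be estimated without values per library.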

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

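The tests of differences between populations after a single treatment, of precision in IM and CD8, and of dendritic cells in the IM gate were chosen only after the result was seen. Effects of the same treatment differed between populations by the test of the difference itself (normal test, adjusted p below 0.05). After the combination this held for 285 genes between IM and TAM, 574 between IM and CD8 and 718 between TAM and CD8. After SBRT it held for 81, 6 and 192 genes, and after IL-12 for 21, 147 and 65. Single outlying libraries could not be looked for without values per library.

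Some lists differed between the same 2 populations in the same direction after all 3 treatments, stated here with the largest of the 3 cameraPR adjusted p-values at a correlation of 0.05. Effects were higher in IM than in TAM for MHC class II (0.0113), cell cycle (9.51e-14), glycolysis and hypoxia (0.000611) and complement and phagocytic receptors (0.0132). They were higher in IM than in CD8 for the interferon gamma response (0.0119), MHC class I (0.00392), MHC class II (0.000203), naive and memory T cell genes (0.00702) and glycolysis and hypoxia (0.0242), and lower for cell cycle (0.00662). Effects were higher in TAM than in CD8 for the interferon gamma response (0.0399), type I interferon (0.00510) and MHC class I (0.0232), and lower for cell cycle (5.45e-27). The controls of a population serve all 3 of its effects, so the 3 tests of a pair are not independent of each other.

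The list of p53 targets passed its test in TAM after SBRT, with 13 of 25 targets called higher, and not in IM (0 of 25) or CD8 (1 of 24, Cdkn1a). Lower precision in IM or CD8 stays open: the targets' standard errors (median ratio 0.819 in IM over TAM, 0.851 in CD8 over TAM) carry each population's shrinkage. The differences passed at a correlation of 0.05 (adjusted p = 9.75e-24 and 5.52e-19). Irradiated tumour or stromal cells carried into the TAM gate stay open too. SBRT added a level of 80338 over the 13 called targets (52405 from Cdkn1a), 15.7 times the 5106 of 24 tumour, ductal and fibroblast markers. Levels of both in such cells are unknown. No biological explanation was tested: the labels give no time of arrival of the cells and no day of harvest, and a difference between cell types in the p53 response itself stays open.

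Cd209a, Flt3, Cd163 and Cx3cr1 fell in IM after IL-12 and after the combination. A loss of conventional dendritic cells as a whole was predicted to lower all their markers by at least the smallest fall of the 4 genes. That fall was -1.12 after IL-12 and -1.46 after the combination. The 9 other dendritic cell markers had a median log2 fold change of 0.22 (SD 0.24) after IL-12 and 0.29 (SD 0.34) after the combination. None lay below -0.19 and -0.24. These 9 were left once Cd209a and Flt3, the dendritic cell markers called lower, were set aside. Markers that monocytes also express would fall less. The values thus show no fall shared by the dendritic cell markers, but do not decide whether dendritic cells were fewer. A smaller share of Cd209a-positive monocyte-derived cells in the gate and regulation within monocytes both stay open. A loss of macrophages stays open too: after the combination Ms4a7 was called lower and C1qa, C1qb and C1qc higher, but these 3 are neighbours at 1 locus and may have risen in the macrophages that remained. Values per cell would be needed to tell them apart.

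Acinar enzyme transcripts were higher in IM and CD8 after each single treatment and not after the combination. A shift of all genes at the same level is argued against, because the median statistic of the acinar markers in CD8 after SBRT (1.20) lay at percentile 99.96 of 10000 random lists matched on level, of which 95% lay between -0.694 and 0.738. Acinar RNA carried over into the sorted cells may account for it: all 15 markers lay above 0, and they scattered about their weighted mean (0.21 ± 0.044, SE) by a chi-square of 1.47 per degree of freedom, below the 95% point of 1.69. The markers are co-regulated, so an alike shift is needed by this explanation but not specific to it. The CD45 gates would remove acinar cells but not free RNA, and a biological cause was not tested.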

How the results depend on the processing

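The alternatives "own standard error of each table" and all settings for the differences between populations after single treatments were chosen only after the data were seen. No paired analysis was possible because the files hold no values per library. For the same reason leaving out each replicate, refits with DESeq2 or with TMM factors, a replicate block and an estimated correlation were planned but not run, and other splits of the samples cannot be made. Depth is unknown, so it cannot be said how far it limits the small counts in TAM, with 2 libraries in 3 of its groups, or in CD8 after SBRT. A chance deviation of a population's controls moves its 3 effects one way and its interaction the other.

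The counts of changed genes, in the order SBRT, IL-12 and combination, were 100, 546 and 1254 in IM, 384, 178 and 725 in TAM and 77, 349 and 1129 in CD8. Requiring a log2 fold change of at least 1 as well gave 5, 80 and 171 in IM, 122, 24 and 156 in TAM and 5, 14 and 58 in CD8. An adjusted p below 0.01 gave 49, 341 and 733 in IM, 195, 93 and 386 in TAM and 12, 105 and 595 in CD8. Both are stricter by construction. The empirical null gave 297 in IM after IL-12 and 336 after the combination, 219 and 247 in TAM after SBRT and the combination, and 1, 24 and 188 in CD8; in IM after SBRT (86) and TAM after IL-12 (178) the count stayed within 1.5 times. Whether broad real change or excess noise widened the statistics is open; the cause was not tested. Adjusting every gene with a p gave 40 in CD8 after SBRT, where more genes are tested. With levels of at least 10 or 50, or median centring, all 9 counts stayed within 1.5 times.

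For differences within a population, requiring an absolute difference of at least 1 gave 38 genes for combination minus SBRT in IM and 8 in CD8, 0 for combination minus IL-12 in CD8, and 0 for the interaction in IM and CD8. A level of at least 50 gave 2 for combination minus SBRT in TAM, 49 in CD8, and 0 for combination minus IL-12 and interaction in CD8, where the gene lost lies below that level. Removing the control variance gave 355, 17 and 4 in IM (minus SBRT, minus IL-12, interaction), 42, 160 and 11 in TAM and 461, 53 and 14 in CD8; on simulated data this test kept near its nominal rate while the main test lay below it. The share of higher genes fell with it from 88% to 50.3% for combination minus SBRT in CD8 and from 85.2% to 61.3% for combination minus IL-12 in TAM; the cause was not tested. The own standard error of each table gave 3 for combination minus SBRT in TAM and 0 for combination minus IL-12 in CD8. In that setting the interaction kept its count of 1 in IM and in CD8, but in each the gene called before was lost (adjusted p = 1.0) and another passed, and in IM the call turned from higher to lower; the cause was not tested. Between populations, an absolute difference of at least 1 gave 277 for IM and CD8 and 446 for TAM and CD8 after the combination, and 89 and 39 for the same pairs after IL-12.

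Of 297 list tests 128 passed, 106 at a correlation of 0.05, 109 by ranks and 104 of 276 with a level of at least 50, and 86 passed in every one of these settings. Among the 134 list results compared, 22 lost their call at a correlation of 0.05, 23 at a level of at least 50 and 25 by ranks, where 6 gained one. The B cell and plasma cell marker list in IM after SBRT turned from lower to higher at a level of at least 50 (median statistic 0.229, adjusted p = 0.788); the cause was not tested. Named genes were called in 389 of 1196 cases, in 350 when every gene with a p was adjusted, 399 at a level of at least 50 and 398 after median centring. Of the 784 named results compared, 39 lost their call when every gene was adjusted, and median centring ended 5 and added 7; at a level of at least 50, 8 of 741 were added.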

Other observations

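No test reported here was planned: all were chosen only after the result was seen, and so were the genes named. After the combination, 6 genes were called higher in IM, TAM and CD8 alike in the authors' deposited tables, against 0.578 for independent lists among 14133 genes tested in all 3. Il12rb1 had log2 fold changes of 2.03, 0.80 and 0.71 in IM, TAM and CD8, and Ly6a 1.94, 0.89 and 1.26. Zbp1 had 0.80, 0.90 and 0.57, and Id2 0.86, 0.66 and 0.59. Glrx (0.86, 0.47 and 0.52) and Phf11d (0.64, 0.64 and 0.35) completed the set. Their largest deposited adjusted p-values were 0.038 and 0.046, and under the empirical null Il12rb1 lost its CD8 call (adjusted p = 0.095).

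The 5 genes called lower in all 3 populations, against 0.252 for independent lists, were Fn1, which encodes fibronectin (-1.66, -1.38 and -0.78), the platelet factor gene Pf4 (-1.68, -1.33 and -0.76), Timp2 (-0.76, -0.90 and -0.87), Acp5 (-0.79, -0.95 and -0.53) and Rgs10 (-0.63, -0.72 and -0.90). Genes called in opposite directions after the combination numbered 17 between IM and TAM, 27 between IM and CD8 and 90 between TAM and CD8. Among the 90 were Mcm2, Mcm3, Mcm4, Mcm5, Mcm7, Cdk1, Bub1 and Aurkb, cell cycle genes that were higher in CD8 and lower in TAM.

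Within a population, the shared controls alone correlate the statistics of 2 treatments. For IL-12 and the combination in IM the correlation across genes was 0.82, against 0.50 in 100 simulations of shared controls. It was 0.72 against 0.50 for SBRT and the combination in TAM and 0.72 against 0.50 for IL-12 and the combination in CD8. The other pairs in IM gave 0.63 against 0.50 (SBRT and IL-12) and 0.62 against 0.50 (SBRT and the combination), and IL-12 and the combination in TAM gave 0.62 against 0.55. SBRT and IL-12 in TAM (0.54 against 0.55), SBRT and the combination in CD8 (0.49 against 0.50) and SBRT and IL-12 in CD8 (0.45 against 0.50) did not exceed the simulated value. Their covariances, in the same order, did exceed it (0.031 against 0.024, 0.030 against 0.016 and 0.022 against 0.015). Genes are not independent replicates, and the controls cannot be split without values per library.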
